A study of Homo sapiens with 12 samples.

How the data were processed

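RNA was measured in 12 libraries of HepaRG cells, 3 each of control, PA, PA+OA and PA+BMS, per the labels. Libraries were made by poly(A) selection and sequenced as 150 bp pairs on an Illumina NovaSeq instrument, per the labels' protocols. The submitters' processing notes name CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3 without saying what each was used for. The genome build, the annotation and the strand setting are not given in the sources used here. The gene identifiers and symbols of all 58735 genes, and the start and end of 58724, equalled those of GENCODE 29 on GRCh38, so coordinates are given on that build.

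The deposited values are FPKM, and no step between reads and FPKM is described in the sources used here. In each library every value multiplied by gene length was a whole multiple of one step (100% of values, tolerance 0.001), so whole reads could be recovered, 16059128 to 19971190 per library. The library size behind the deposited FPKM differed from this total by a factor of 0.827 to 1.14, whose origin no source gives. A gene counted in 3 reads is taken as the floor of detection. FPKM is not a count, so no count model was used for the main results, and a fit of limma voom on the recovered reads was added as an alternative.

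From the deposited FPKM, log2(FPKM + 1) was tested for genes of at least 1 FPKM in at least 3 libraries with limma 3.58.1 in R 4.3.3, with one coefficient per group over all 12 libraries, 8 residual degrees of freedom, eBayes with a trend and Benjamini-Hochberg adjustment within each of 6 comparisons at 0.05. Tests are two-sided. Lists were tested with camera at a preset correlation of 0.01, adjusted over 29 lists within a comparison, and again with an estimated correlation; fry was run beside them. Counts adjusted over a list alone use its members' p-values only. The design, the lists and the alternatives, other than 3 added later, were fixed before the data were examined. Which of the lists are described in which comparison was chosen after their results were seen.

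Genes were named by a rule fixed at the same time. It takes the 6 protein-coding genes with the largest rise and the 6 with the largest fall among those called, with a mean of at least 1 FPKM in a group and no overlap between groups, in PA against control, PA+OA against PA and PA+BMS against PA. It adds 2 to 4 members of each described list with the smallest p, and 17 fixed genes in every comparison. The other comparisons use the fixed genes and genes named in those 3, of which the ones printed were selected after their values were seen, and PA+BMS against PA+OA also takes the 3 largest rises and falls. CPS1, HPD, the histone genes and the markers PDGFRB, CSF1R and CDH5 were singled out after their values were seen. The list values within control replicate 1 were added after the data were seen. Of 163 genes that the rule reaches, 100 overlap another annotated gene and 53 overlap one that reached 1 FPKM in a library, so shared reads are uncertain. Some genes that the rule reaches are not reported here.

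Replicates of a group differed by more than sampling noise in all 12 pairs (chi-square per gene 3.46 to 67.6), so none was treated as a repeat deposit. The procedure was tested on reads simulated with an assumed dispersion of 0.01, which was not estimated from the libraries, and 200 changed genes in each comparison, over 11385 to 11420 tested genes. In these, 90.0% to 95.0% of 2-fold and 50.0% to 66.0% of 1.5-fold changes were recovered, and 4.05% to 5.77% of calls were false. Simulated genes varied independently, with no GC trend and no library that stood apart, so these rates need not hold for the real libraries. Alternatives were a pseudocount of 0.1, no filter and a filter at 5 FPKM, median-of-ratios scaling, library totals set equal, quantile normalization, only the 2 groups compared, a replicate block, precision weights, robust eBayes, protein-coding genes alone, and leaving out each library in turn. After the data were seen, 3 were added: removal of each library's trend with GC content and gene length (natural splines with 5 degrees of freedom), voom on recovered reads, and leaving out both PA+OA replicate 1 and PA+BMS replicate 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.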

Results

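The 12 libraries came from HepaRG cells, a human hepatic line whose cells can take on hepatocyte-like or bile duct-like states in culture, and the series title places the work in liver fibrosis. Each of 4 groups had 3 libraries. Control cells were untreated, the PA group received 400 µM deuterium-labelled palmitate, a saturated fatty acid, for 4 h, and the PA+OA group received the same palmitate together with 200 µM oleate, a monounsaturated fatty acid. In the PA+BMS group, cells had 50 µM BMS-309403, an inhibitor of the fatty acid-binding protein FABP4, for 24 h and palmitate for 4 h. Messenger RNA was measured as FPKM for 58735 annotated genes on GRCh38, and 11856 genes reached 1 FPKM in at least 3 libraries and were tested. The whole reads behind the values summed to between 16059128 and 19971190 per library. Labels do not call the replicates separate cultures, so main p-values use a spread, pooled over 4 unequally noisy groups, that may be technical.

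Genes of mature hepatocytes were low in every group. Of 28 hepatocyte genes on the list, 26 stayed under 1 FPKM in all 12 libraries, and the exceptions, named after their values were seen, were CPS1, a urea cycle enzyme, and HPD, of tyrosine breakdown. No read of ALB, the albumin gene (ENSG00000163631, chromosome 4, 73397114 to 73421412), or of FABP1, the liver fatty acid-binding protein, was counted in any library, where 3 reads would have been worth at most 0.0586 and 0.0801 FPKM. FABP4 (ENSG00000170323, chromosome 8, 81478419 to 81483263), the stated target of BMS-309403, had 4 reads over all 12 libraries and at most 0.0864 FPKM, below its 3-read level of up to 0.142. PLIN2, a lipid droplet coat protein, had 8 reads in all, and CD36, a fatty acid transporter, lay between 0.0567 and 0.182 FPKM. None of these 5 genes reached the level needed for testing, so no comparison gives a change for them. Levels are given as mean ± SD of the 3 libraries of a group, and log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Intervals and floors from reads cover counting error only.

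The libraries also differed along an axis that followed the GC content of transcripts. The first principal component held 54.4% of the variance, and its gene loadings followed transcript GC content (Spearman 0.68 across genes, which are not independent replicates). PA+OA replicate 1, at 54.6, and PA+BMS replicate 3, at -51.5, lay at its opposite ends, each apart from the rest of its group, and are meant by the libraries that stand apart. Control replicate 1 also differed from the other controls, at -5.70 on this component against -27.1 and -24.6. Its counts differed from theirs by a chi-square per gene of up to 22.7, against 7.73 between controls 2 and 3. In control replicate 1, 23 of 25 integrated stress response genes and 14 of 17 immediate early genes were higher than in both other controls, as were 24 of 27 ribosomal protein genes. Of 15 heat shock genes, 14 were lower there, with HSPA1A at 65.1, 212 and 195 FPKM in control replicates 1, 2 and 3. GC content and gene length together explained 43.3% of the variance of log2 fold changes in PA against control, 7.79% in PA+OA against PA and 55.7% in PA+BMS against PA. The median GC content of genes that rose and that fell was 57.5% and 41.4% with palmitate, and 41.5% and 58.1% with BMS-309403 on top of palmitate. Mitochondrial ribosomal RNA took 0.674% ± 0.0953 of reads in control, 0.795% ± 0.163 in PA, 1.75% ± 0.309 in PA+OA and 1.03% ± 0.415 in PA+BMS (SD, n = 3). Counts are therefore also given with each library's trend against GC content and length removed, and without PA+OA replicate 1 and PA+BMS replicate 3, both chosen after the data were seen.

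**Figure D1:**
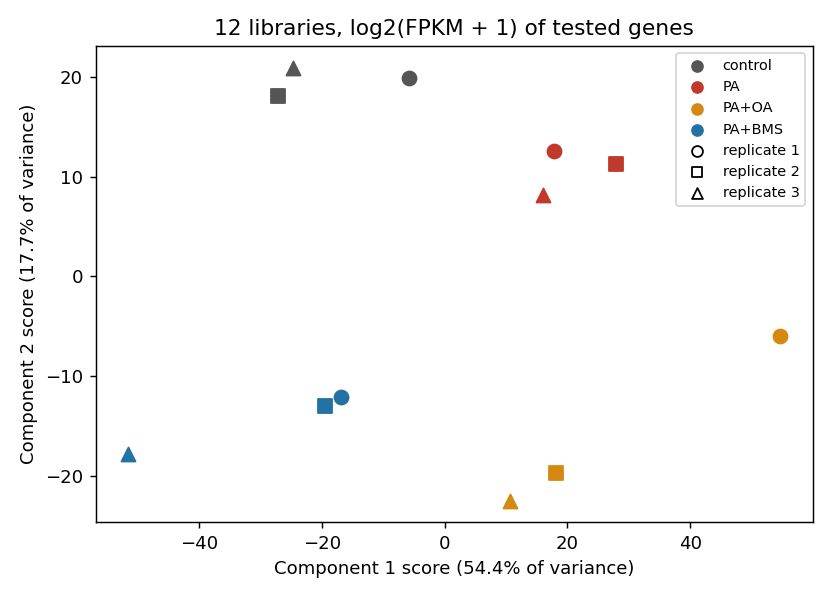
Scores of the 12 libraries on the first and second principal components of log2(FPKM + 1) over the 11856 tested genes, with colour for the group and marker shape for the replicate number. PA+OA replicate 1 (component 1 score 54.6) and PA+BMS replicate 3 (-51.5) sit apart from the other libraries of their groups.

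The comparison of PA with control asked what 4 h of palmitate did to expression. ANGPTL4, a secreted inhibitor of lipoprotein lipase (ENSG00000167772, chromosome 19, 8363289 to 8374373), rose from 7.33 ± 0.269 to 105 ± 8.89 FPKM (log2 fold change 3.67, SE 0.21, adjusted p = 2.76e-06), the largest rise under the rule for named genes. CHAC1, which degrades glutathione (ENSG00000128965, chromosome 15, 40952962 to 40956519), rose from 12.9 ± 17.7 to 82.3 ± 9.59 FPKM (log2 fold change 3.43, SE 0.66, adjusted p = 0.00594), and the stress-induced SESN2 from 6.37 ± 7.41 to 49.7 ± 4.47 (log2 fold change 3.25, SE 0.47, adjusted p = 0.00170). The transcription factors JUN and ATF3 rose by 2.72 (SE 0.11, adjusted p = 1.81e-07) and 2.48 (SE 0.26, adjusted p = 0.000278) on the log2 scale, and the stress cytokine GDF15 rose from 32.6 ± 20.1 to 162 ± 36.3 FPKM. Control replicate 1 carried the control means of CHAC1 (33.4, 3.38 and 2.04 FPKM in replicates 1, 2 and 3), SESN2 (14.9, 2.37 and 1.82) and GDF15 (55.8, 21.9 and 20.0). Without it their log2 changes were 4.51, 4.03 and 2.87 (limma adjusted p = 6.10e-06, 4.23e-07 and 0.000309). The falls selected by the same rule were AATK, a membrane kinase (log2 fold change -1.68, SE 0.11, adjusted p = 7.39e-06), CHML, a Rab escort protein (log2 fold change -1.66, SE 0.25, adjusted p = 0.00187), and DKK1, a secreted Wnt inhibitor, which fell from 33.7 ± 5.83 to 10.6 ± 1.17 FPKM. AATK overlaps BAIAP2 and CHML overlaps OPN3 in the annotation, so how reads were divided there is uncertain. TENT5A, the Wnt ligand WNT5A and the zinc importer SLC39A10 fell as well, with log2 changes of -1.41, -1.39 and -1.29.

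Genes of the integrated stress response, a programme induced when phosphorylated eIF2-alpha slows translation, rose together: of 25 measured members, 21 rose and 0 fell (21 and 0 adjusted over the list alone; median log2 change 0.95). This list passed the set test (camera adjusted p = 5.95e-10, and adjusted p = 0.289 with an estimated correlation). TRIB3, a stress pseudokinase, rose from 57.3 ± 19.1 to 233 ± 17.3 FPKM and PPP1R15A, which directs eIF2-alpha dephosphorylation, from 20.1 ± 9.01 to 86.3 ± 7.93. ASNS, asparagine synthetase, rose by 0.77 and DDIT3, which encodes CHOP, by 1.93 (SE 0.41, adjusted p = 0.00912) on the log2 scale. Without control replicate 1, in which most of these genes were higher than in the other controls, 20 and 0 rose and fell, and DDIT3 (14.0, 3.68 and 2.43 FPKM in control replicates 1, 2 and 3) was at 2.56. Of 17 immediate early genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 1.02e-10, and adjusted p = 0.289 with an estimated correlation), among them KLF2 at 2.29, EGR1 at 2.36 and FOS at 1.12. Of 15 NF-kB inflammatory genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.00329, and adjusted p = 0.289 with an estimated correlation). The neutrophil chemokine CXCL8 rose from 0.253 ± 0.0681 to 3.66 ± 1.43 FPKM, and the cytokines IL6 and LIF and the inhibitor NFKBIA rose by 0.96, 0.58 and 0.89. With the GC and length trend removed, the members that rose and fell numbered 19 and 0 for the integrated stress response, 14 and 0 for immediate early genes and 6 and 0 for NF-kB genes.

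Of 14 lipid droplet and triglyceride genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0284, and adjusted p = 0.289 with an estimated correlation), with FITM2, of lipid droplet formation, up by 0.57, PNPLA2, the adipose triglyceride lipase, up by 0.80 and DGAT1, which makes triglyceride, up by 0.63; with the trend removed 5 and 0 did so. In fatty acid oxidation and PPAR targets 3 of 21 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.132). CPT1A, which imports fatty acids into mitochondria, rose from 28.5 ± 2.41 to 37.9 ± 3.03 FPKM (adjusted p = 0.0409), while the medium-chain dehydrogenase ACADM fell by 0.60 on the log2 scale. Of 25 cholesterol genes, 9 rose and 2 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.0995; 8 and 0 with the trend removed). MVK, mevalonate kinase, rose by 0.98, whereas HMGCS1, an early mevalonate enzyme, fell from 5.74 ± 1.52 to 3.23 ± 0.436 FPKM (adjusted p = 0.0305). Of 12 fatty acid binding and uptake genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.638), where SLC27A2, an acyl-CoA synthetase, fell by 0.52 and SCP2, a sterol carrier, fell by 0.41. The median of this list, 0.045, was -0.18 with library totals set equal and -0.065 under quantile normalization, and its mean was -0.070.

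The heat shock list fell: of 15 members, 0 rose and 5 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.0340, and adjusted p = 0.543 with an estimated correlation; 0 and 5 with the trend removed), among them the co-chaperone DNAJA1 at -0.87 and HSPD1, a mitochondrial chaperonin, at -0.82. In the list of ER chaperones and the unfolded protein response 4 of 22 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.204), and its median of 0.12 turned negative under quantile normalization (-0.066) and with library totals set equal (-0.13). XBP1 rose by 1.03 and HERPUD1, of ER-associated degradation, by 1.48, and HSPA5, the main ER chaperone, was at 0.23 ± 0.15. Among p53 and apoptosis genes 7 of 17 rose and 3 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.207). CDKN1A changed by 1.97 and GADD45A by 2.21. The interferon list had 7 falls and 1 rise among 14 members (3 and 7 adjusted over the list alone; camera adjusted p = 0.341), led by IFIT3 at -1.15 and IFIT1 at -1.07.

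In the extracellular matrix and fibrosis list 4 of 19 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.158; 2 and 1 with the trend removed). Its median of 0.22 became -0.045 with library totals set equal. CYR61 and CTGF, matricellular targets of YAP signalling, rose by 1.78 and 0.89, and LOX, a collagen cross-linking enzyme, fell by 0.53. COL1A1 (0.21 ± 0.10), TGFB1 (0.32 ± 0.17), ACTA2 (0.078 ± 0.12), SCD (0.40 ± 0.16) and PDK4 (0.63 ± 0.26) did not pass the test (log2 change ± SE). Cytosolic ribosomal proteins and mitochondrially encoded genes passed the set test upward (camera adjusted p = 0.00267, and adjusted p = 0.636 with an estimated correlation for the first; camera adjusted p = 0.00986, and adjusted p = 0.582 with an estimated correlation for the second), although 1 of 27 rose and 0 fell and 2 of 13 rose and 0 fell (0 and 0 adjusted over the list alone for each). RPL3 rose by 0.50, MT-ND3 by 0.55 and MT-CO2 by 0.58, while RPL13 was at 0.59 ± 0.21. Without the libraries that stand apart, 20 and 0 ribosomal protein genes and 11 and 0 mitochondrial genes rose and fell, and with the trend removed 0 and 0 and 3 and 0.

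In all, limma called 3272 of 11856 genes in PA against control at an adjusted p of 0.05, 1518 that rose and 1754 that fell, and 149 of them changed at least 2-fold. This 2-fold count, on the log2(FPKM + 1) scale, was 458 with a pseudocount of 0.1, 421 with library totals set equal, 99 with the trend removed and 529 with voom, and 280 without control replicate 1. With the GC and length trend removed 1948 were called, of which 1322 were among the 3272, and without both libraries that stand apart 6687. The count fell to 798, 992, 1453, 900 and 2027 without control replicates 2 and 3 and PA replicates 1, 2 and 3 in turn, and rose to 5348 without PA+OA replicate 1. With library totals set equal, which moved the median of all genes to -0.18 from 0.028, 518 rose and 2901 fell. Of the 46 calls named here, 35 held in all 12 fits that left out a library, and 40 held with the trend removed. Leaving out control replicate 2, control replicate 3 or PA replicate 2 ended 11, 11 and 11 of them. In PA against control, calls lost in some of these fits were CPT1A, CTGF, DGAT1, HMGCS1, HSPD1, LOX, MT-CO2, MT-ND3, PNPLA2, RPL3 and SCP2 (highest limma adjusted p 0.0517 to 0.162), also without PA replicate 1 (7), PA replicate 3 (6), PA+BMS replicate 1 (4), PA+BMS replicate 2 (4), control replicate 1 (3) and PA+OA replicate 2 (3). With the trend removed, CPT1A, HMGCS1, LIF, LOX, RPL3 and SCP2 were no longer called (adjusted p 0.0510 to 0.535). PDK4 (0.98, adjusted p = 0.0102) and SCD (0.48, adjusted p = 0.0157) passed the test with the trend removed, though not as deposited. COL1A1 (0.21, adjusted p = 0.0191), PDK4 (0.63, adjusted p = 0.00112), RPL13 (0.59, adjusted p = 0.00187), SCD (0.40, adjusted p = 0.00714) and TGFB1 (0.32, adjusted p = 0.0144) passed the test without both libraries that stand apart, though not as deposited. List members that rose and fell numbered 5 and 1 for ER chaperone genes and 1 and 4 for interferon genes with the trend removed. They numbered 9 and 1 for lipid droplet genes, 10 and 1 for oxidation and PPAR targets, 15 and 6 for cholesterol genes, 1 and 4 for binding and uptake genes, 9 and 4 for ER chaperone genes, 9 and 6 for p53 genes, 6 and 7 for interferon genes and 10 and 3 for matrix genes without the libraries that stand apart. Leaving out a library moved by over 1.5 times the number of integrated stress response genes that rose (13 without control replicate 2) and NF-kB genes that rose (4 to 5 without control replicates 2 or 3 or PA replicates 1 or 2). It also moved lipid droplet genes that rose (1 to 2 without control replicates 2 or 3 or PA replicates 1 or 2, and 9 without PA+OA replicate 1) and heat shock genes that fell (1 without control replicates 2 or 3 or PA replicate 2, and 9 without control replicate 1). Moved alike were ribosomal protein genes that rose (7 to 10 without PA+OA replicate 1 or PA+BMS replicate 3) and mitochondrial genes that rose (6 without PA+BMS replicate 3). Oxidation and PPAR targets had 1 rise without control replicates 2 or 3 or PA replicates 1, 2 or 3 or PA+OA replicate 2 or PA+BMS replicates 1 or 2 and 8 rises without PA+OA replicate 1. Cholesterol genes had 3 rises without control replicates 2 or 3 or PA replicate 2, 14 rises without PA+OA replicate 1 and 4 falls without PA+OA replicate 1 or PA+BMS replicate 3. ER chaperone genes had 8 to 9 rises without PA+OA replicate 1 or PA+BMS replicate 3 and 0 to 1 falls without control replicates 2 or 3 or PA replicates 1, 2 or 3. The p53 genes had 5 falls without PA+BMS replicate 3. Interferon genes had 5 rises without PA+OA replicate 1 and 3 to 4 falls without control replicates 2 or 3 or PA replicates 1 or 2. Matrix genes had 1 to 2 rises without control replicates 2 or 3 or PA replicates 1, 2 or 3 and 8 rises and 3 falls without PA+OA replicate 1.

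**Figure D2:**
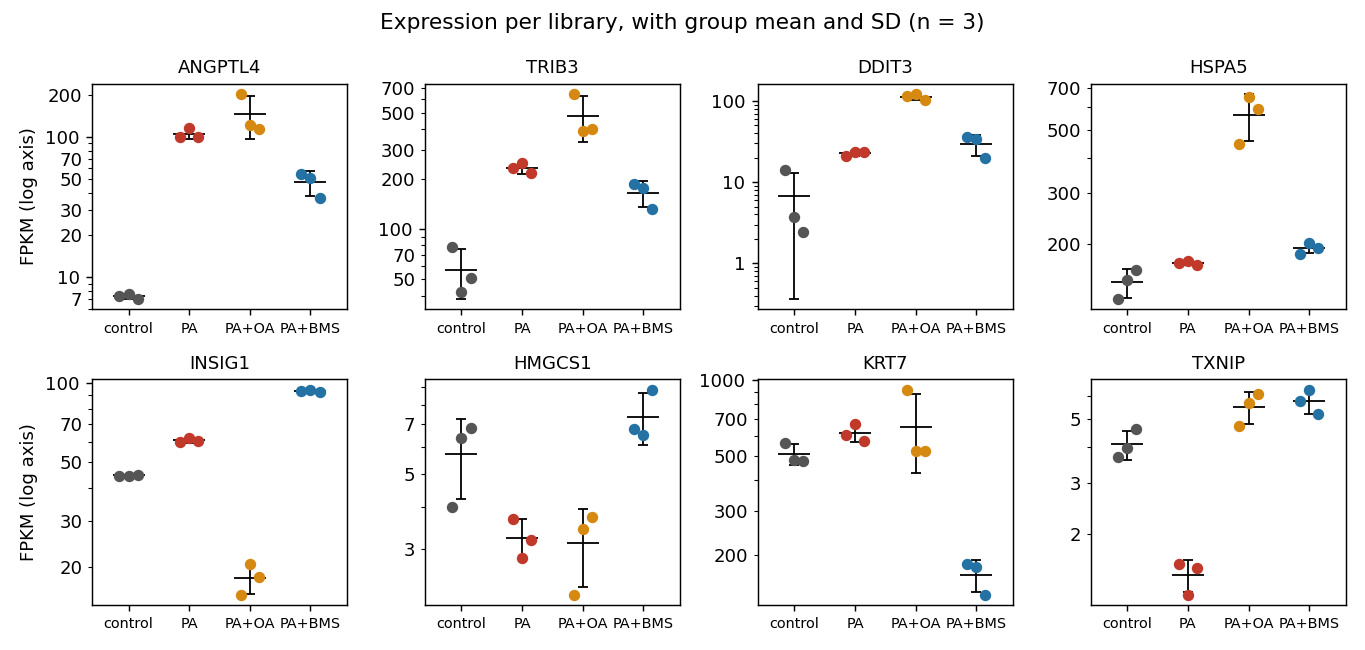
FPKM on a log axis in each library for ANGPTL4, TRIB3, DDIT3, HSPA5, INSIG1, HMGCS1, KRT7 and TXNIP, by group, with points for libraries, a bar for the group mean and whiskers for the SD (n = 3). ANGPTL4 lay at 7.33 ± 0.269 in control and 105 ± 8.89 in PA, HSPA5 reached 563 ± 107 in PA+OA, and INSIG1 fell to 18.1 ± 2.38 there.

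The comparison of PA+OA with PA asked what oleate added to palmitate changed; the added oleate also raised the total fatty acid from 400 to 600 µM, and no group received oleate alone. HSPA5, the main chaperone of the endoplasmic reticulum (ENSG00000044574, chromosome 9, 125234853 to 125241330), rose from 171 ± 2.46 to 563 ± 107 FPKM (log2 fold change 1.70, SE 0.15, adjusted p = 6.33e-05). DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737) rose from 22.7 ± 1.51 to 113 ± 9.55 (log2 fold change 2.26, SE 0.41, adjusted p = 0.00550), although it overlaps MARS in the annotation and shared reads there are uncertain. INSIG1, a sterol-regulated ER anchor, fell from 60.7 ± 1.21 to 18.1 ± 2.38 (log2 fold change -1.70, SE 0.11, adjusted p = 4.24e-06). The other leading rises were the inducible heat shock genes HSPA6, from 0.779 ± 0.0800 to 24.6 ± 3.70 FPKM, and HSPA1A, by 2.47, and the histone genes HIST1H2AC (log2 fold change 2.58, SE 0.18, adjusted p = 1.22e-05), HIST1H2BJ at 2.35 and HIST1H2BO at 2.26. Further falls were MT-ND6, a mitochondrial complex I subunit, from 1106 ± 214 to 269.6 ± 33.8 FPKM, the basement membrane genes HSPG2 at -1.62 and LAMA5 at -1.46, and CHPF2, of chondroitin synthesis, at -1.26. HSPA1A with HSPA1B, and the histone genes, have near-identical copies, so how reads were divided among them is uncertain.

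ER chaperone and unfolded protein response genes rose: of 22, 9 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 7.38e-11, and adjusted p = 0.00885 with an estimated correlation; 15 and 0 without the libraries that stand apart). DNAJB9 rose by 2.25, HERPUD1 by 2.20 and MANF, a secreted ER stress protein, by 0.91 on the log2 scale. Cholesterol synthesis and uptake genes fell, 8 of 25, and none rose (0 and 10 adjusted over the list alone; camera adjusted p = 1.34e-08, and adjusted p = 0.0176 with an estimated correlation; 0 and 17 without those libraries). MSMO1, a sterol oxidase, fell by 0.92. HMGCS1 was at -0.053 ± 0.19 (log2 change ± SE). The heat shock list rose (5 of 15 rose and 0 fell; 9 and 0 adjusted over the list alone; camera adjusted p = 1.21e-07, and adjusted p = 0.207 with an estimated correlation). The co-chaperones BAG3 changed by 1.34 and DNAJB1 by 1.61.

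In the integrated stress response list 7 of 25 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 3.94e-05, and adjusted p = 0.360 with an estimated correlation). The hormone FGF21 rose by 1.77, ATF3 by 1.72, ASNS by 1.003 and TRIB3 from 233 ± 17.3 to 479 ± 146 FPKM (adjusted p = 0.0275). Immediate early genes rose in 5 of 17 cases and none fell (6 and 0 adjusted over the list alone; camera adjusted p = 4.25e-05, and adjusted p = 0.285 with an estimated correlation), led by JUN at 0.91 and DUSP6, a MAP kinase phosphatase, at 1.11. Among NF-kB genes 6 of 15 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00122, and adjusted p = 0.207 with an estimated correlation): IL1A at 1.28 and CXCL3 at 1.11 rose, LIF at -0.73 fell, and CXCL8 rose from 3.66 ± 1.43 to 8.63 ± 0.418 FPKM (adjusted p = 0.00401). In p53 and apoptosis genes 3 of 17 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00616, and adjusted p = 0.0932 with an estimated correlation). GADD45A changed by 1.60 and PLK3 by 0.94.

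Mitochondrially encoded genes passed the set test downward, with 3 of 13 past the test and none up (0 and 3 adjusted over the list alone; camera adjusted p = 0.00122, and adjusted p = 0.499 with an estimated correlation). MT-ND3 fell by 0.81 and MT-CO2 by 0.76, while the share of reads from mitochondrial ribosomal RNA was 2.20 times that in PA (SE 0.34). Histone genes as a class, a group chosen after their values were seen, rose in 19 of 30 measured cases and none fell (median log2 change 1.15). Without PA+OA replicate 1, 22 were measured and 13 rose, so some of the 30 reached the tested level only with that library. The filter can thus favour genes that are high in PA+OA. Among fatty acid synthesis and desaturation genes 0 of 19 rose and 3 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.0573): FASN, the fatty acid synthase, fell by 1.11, ACLY by 0.43 and SCD, which makes oleate, from 309 ± 41.9 to 185 ± 31.8 FPKM (adjusted p = 0.0149). PDK4, a brake on pyruvate oxidation, fell by 0.97 (adjusted p = 0.0389), the only called member of 21 oxidation and PPAR targets (0 and 0 adjusted over the list alone; camera adjusted p = 0.882), with ANGPTL4 at 0.43 ± 0.21 and CPT1A at -0.11 ± 0.13. In the matrix list 2 of 19 rose and 3 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.0704): COL5A1 fell by 1.04 and COL4A2 by 0.82, and CTGF rose by 1.48. COL1A1 (-0.13 ± 0.10), TGFB1 (-0.17 ± 0.17) and ACTA2 (0.10 ± 0.12) did not pass the test.

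In total 938 genes were called between PA+OA and PA, 475 that rose and 463 that fell, and 137 changed at least 2-fold. This 2-fold count, on the log2(FPKM + 1) scale, was 247 with a pseudocount of 0.1, 84 with protein-coding genes alone and 260 with voom. With the GC and length trend removed 1583 were called, which held 817 of the 938, and without both libraries that stand apart 2977. The count was 472, 511 and 589 without PA replicates 1, 2 and 3, 465 and 553 without PA+OA replicates 2 and 3, and 1900 without PA+OA replicate 1. Of 39 named calls, 31 held in all 12 fits that left out a library and 39 with the trend removed. In PA+OA against PA, calls lost in some of these fits were ACLY, MT-CO2, MT-ND3, PDK4, SCD and TRIB3 (highest limma adjusted p 0.0710 to 0.138), without PA replicate 1 (6), PA replicate 2 (5), PA+OA replicate 2 (4), PA replicate 3 (3), PA+OA replicate 3 (3), PA+BMS replicate 2 (2), control replicate 1 (1), control replicate 2 (1), control replicate 3 (1) and PA+BMS replicate 1 (1). CXCL3 and DUSP6 fell under the tested level, and were not tested, when any PA+OA library was left out. ANGPTL4 (0.43, adjusted p = 0.0123) passed the test with the trend removed, though not as deposited. TGFB1 (-0.39, adjusted p = 0.0222) passed the test without both libraries that stand apart, though not as deposited. List members that rose and fell numbered 5 and 1 for p53 genes with the trend removed. They numbered 8 and 0 for heat shock genes, 5 and 1 for p53 genes, 0 and 6 for mitochondrial genes, 0 and 5 for fatty acid synthesis genes and 3 and 8 for matrix genes without the libraries that stand apart. Dropping a library moved by over 1.5 times the number of cholesterol genes that fell (4 without PA replicate 1 or PA+OA replicate 2) and immediate early genes that rose (3 without PA+OA replicates 2 or 3). It also moved NF-kB genes that rose (2 to 3 without PA+OA replicates 2 or 3) and p53 genes that rose (5 without control replicate 1 or PA+OA replicate 1). Moved alike were mitochondrial genes that fell (1 without PA replicates 1 or 2 or PA+OA replicates 2 or 3). Fatty acid synthesis genes had 1 fall without PA replicate 1 and 5 falls without PA+OA replicate 1. Matrix genes had 5 falls without PA+OA replicate 1. Of the 3272 genes that palmitate changed, 130 (3.97%) moved back toward control with oleate and 170 (5.20%) moved further away. Independent lists would share 129.6 and 129, so 130 is no excess. With no effect simulated, the median was 0, the highest 203 and 1 of 100 was as large. Mostly 0 by design, this cannot judge 130. With the trend removed 107 of 1948 moved back, without both libraries that stand apart 1474 of 6687, and without PA+OA replicate 1 alone 783 of 5348. The number was lower without control replicate 2 (28 of 798) or 3 (44 of 992), PA replicate 1 (28 of 1453), 2 (29 of 900) or 3 (66 of 2027), PA+OA replicate 2 (49 of 2968) or 3 (62 of 3408) and PA+BMS replicate 2 (82 of 2739), and higher without PA+BMS replicate 3 (207 of 4166). Both comparisons use the same PA libraries, too few to split, so part of any excess may come from them.

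PA+BMS against PA tested BMS-309403 under palmitate. It was present for 24 h and palmitate for 4 h. No group had BMS-309403 alone, so its own effect cannot be told from one on palmitate's action. With 4 FABP4 reads in all, no call here is read as FABP4 inhibition. KRT7, a keratin of bile duct epithelium (ENSG00000135480, chromosome 12, 52232520 to 52252186), fell from 614 ± 49.7 to 167 ± 24.6 FPKM (log2 fold change -1.88, SE 0.21, adjusted p = 0.000631). TGM2, transglutaminase 2 (ENSG00000198959, chromosome 20, 38127387 to 38166578), fell from 41.6 ± 2.83 to 8.42 ± 1.42 (log2 fold change -2.19, SE 0.17, adjusted p = 4.68e-05), and ALPI, the intestinal alkaline phosphatase, from 393 ± 34.6 to 88.9 ± 6.80 (log2 fold change -2.13, SE 0.16, adjusted p = 4.43e-05). The interferon-induced OASL and ISG15 fell by 2.07 and 1.95 on the log2 scale, and TNS4, a focal adhesion protein, by 1.92. KRT7 and TGM2 overlap genes on the other strand, and the strand setting of the counting is not given in the sources used here, so shared reads are uncertain. TXNIP, a thioredoxin-binding regulator of glucose uptake, rose from 1.44 ± 0.182 to 5.78 ± 0.558 FPKM (log2 fold change 1.47, SE 0.12, adjusted p = 5.19e-05). The other leading rises were NCOA7 at 1.42, TIPARP, a target of the aryl hydrocarbon receptor, at 1.38, the glucocorticoid receptor NR3C1 at 1.33, PEG10 at 1.31 and ABCC2, a bile canalicular exporter, at 1.25.

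Cytosolic ribosomal protein genes fell in 23 of 27 cases and none rose (0 and 23 adjusted over the list alone; median -0.76; camera adjusted p = 3.47e-05, and adjusted p = 0.794 with an estimated correlation; 0 and 20 rose and fell with the trend removed). RPL3 changed by -0.78 and RPS16 by -0.93. Extracellular matrix and fibrosis genes fell in 10 of 19 cases and none rose (0 and 10 adjusted over the list alone; camera adjusted p = 0.0116, and adjusted p = 0.794 with an estimated correlation; 0 and 5 with the trend removed). Markers of other cell types fell with them: 1 of 2 stellate, 1 of 1 macrophage, 1 of 1 endothelial and 3 of 5 cholangiocyte markers (camera adjusted p = 0.385, 0.335, 0.385 and 0.293). COL4A2 fell by 0.86, COL5A1 by 0.73, TGFBI by 0.70 and fibronectin, FN1, by 0.70. COL1A1 fell by 0.28 (adjusted p = 0.0270) and TGFB1 by 0.47 (adjusted p = 0.0322), and ACTA2 was at -0.16 ± 0.12. The direction of COL1A1 turned to 0.066 with library totals set equal, and with the trend removed COL1A1 was at 0.093 and TGFB1 at 0.12, neither called (adjusted p = 0.316 and 0.306). Nuclear oxidative phosphorylation genes passed the set test downward, where 2 of 25 rose and 13 fell (2 and 13 adjusted over the list alone; camera adjusted p = 0.0390, and adjusted p = 0.794 with an estimated correlation). SDHA changed by -0.70, and UQCRC2, which rose, by 0.51. With the trend removed these numbers were 0 and 11.

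Cholesterol genes were split, and 9 of 25 rose and 7 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.665; 8 and 1 with the trend removed). Its median of -0.18 had the opposite sign to the set test, and became 0.19 with library totals set equal. IDI1 rose by 0.89, SC5D by 0.87, MSMO1 by 0.88, and HMGCS1 rose from 3.23 ± 0.436 to 7.37 ± 1.29 FPKM (adjusted p = 0.00470). In the fatty acid binding and uptake list 2 of 12 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.896): ACSL5, an acyl-CoA synthetase, fell by 0.88 and SCP2 rose by 0.58. Among NRF2 targets 5 of 19 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.841; 9 and 2 with the trend removed), with the thioredoxin reductase TXNRD1 up by 0.85 and ABCC3 down by 0.72. The interferon list had 1 rise and 5 falls among 14 members (1 and 5 adjusted over the list alone; camera adjusted p = 0.456). OAS1 changed by -0.67 beside ISG15. In the integrated stress response list 5 of 25 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.665; 1 and 3 with the trend removed). The tRNA synthetase WARS changed by -0.72, VLDLR by 0.64 and the cystine transporter SLC7A11 by 1.19. With library totals set equal the medians of these 4 lists turned from -0.025 to 0.28 (binding and uptake), -0.13 to 0.25 (NRF2), -0.16 to 0.10 (interferon) and -0.37 to 0.004 (integrated stress response). ANGPTL4 fell from 105 ± 8.89 to 47.5 ± 9.64 FPKM (adjusted p = 0.00366). DDIT3 (0.34 ± 0.41), TRIB3 (-0.51 ± 0.24), HSPA5 (0.17 ± 0.15), CXCL8 (-0.22 ± 0.19), SCD (-0.017 ± 0.16), CPT1A (0.22 ± 0.13) and PDK4 (0.39 ± 0.26) did not pass the test.

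Between PA+BMS and PA 6463 genes were called, 2982 that rose and 3481 that fell, and 282 changed at least 2-fold. This 2-fold count, on the log2(FPKM + 1) scale, was 1015 with a pseudocount of 0.1, 923 with library totals set equal, 87 with the trend removed and 1152 with voom, and 567 without PA+BMS replicate 1, 519 without PA+BMS replicate 2, 131 without PA+BMS replicate 3 and 133 without both libraries that stand apart. With the GC and length trend removed the number was 2750, which held 1930 of the 6463, and without both libraries that stand apart it was 6508. It was 3698 without PA replicate 2 and 3703 without PA+BMS replicate 3. With library totals set equal, which moved the median of all genes to 0.24 from -0.044, 4584 rose and 1202 fell. Of 35 named calls, 33 held in all 12 fits that left out a library and 30 with the trend removed. Between PA+BMS and PA, calls lost in some of these fits were COL1A1 and TGFB1 (highest limma adjusted p 0.0720 to 0.1003), without PA replicate 1 (2), PA replicate 2 (2), PA+BMS replicate 2 (2), PA+BMS replicate 3 (2) and PA replicate 3 (1). With the trend removed, COL1A1, SCP2, TGFB1, UQCRC2 and VLDLR were no longer called (adjusted p 0.0601 to 0.316). List members that rose and fell numbered 1 and 1 for binding and uptake genes with the trend removed. A library left out moved by over 1.5 times the number of ribosomal protein genes that fell (10 to 11 without PA replicate 2 or PA+BMS replicate 3) and nuclear oxidative phosphorylation genes that fell (5 to 6 without PA replicate 2 or PA+BMS replicate 3). Cholesterol genes had 3 falls without PA replicates 1 or 2 or PA+BMS replicate 3. Binding and uptake genes had 1 fall without PA replicates 1 or 2. NRF2 targets had 2 falls without PA replicates 1 or 2 or PA+BMS replicate 3. Interferon genes had 3 falls without PA replicate 2 or PA+BMS replicate 3. Integrated stress response genes had 3 rises without PA replicates 1 or 2 or PA+BMS replicate 2. Of the 3272 palmitate-changed genes, 2274 (69.5%) moved back and 63 (1.93%) moved further. Independent lists would share 887 and 897. With no effect simulated, the median was 0 and 1 of 100 was as large, at 4615. This exceeds 3272, so the simulated list differed and cannot judge 2274. The PA libraries could not be split. With the trend removed, 581 of 1948 (29.8%) moved back. Leaving out a library gave 480 of 798 (60.2%) for control replicate 2, 617 of 992 (62.2%) for control replicate 3, and 820 of 1453 (56.4%), 412 of 900 (45.8%) and 1323 of 2027 (65.3%) for PA replicates 1, 2 and 3. It gave 1851 of 4166 (44.4%) without PA+BMS replicate 3, 4158 of 5348 (77.7%) without PA+OA replicate 1 and 4619 of 6687 (69.1%) without both.

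**Figure D3:**
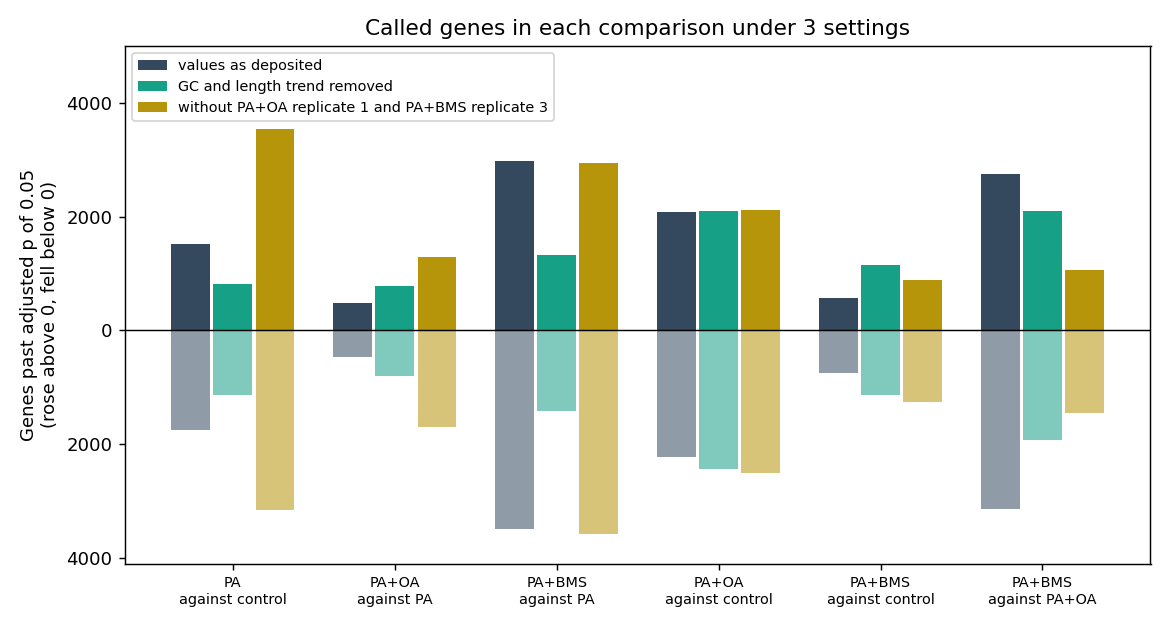
Number of genes past an adjusted p of 0.05 in each of the 6 comparisons, with rises above 0 and falls below 0, for values as deposited, for values with the GC and length trend removed, and without PA+OA replicate 1 and PA+BMS replicate 3. Between PA+BMS and PA the total is 6463, 2750 and 6508 under these settings.

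Against control, the PA+OA libraries asked how cells with both fatty acids differed from untreated cells. In the integrated stress response list 20 of 25 rose and 1 fell (20 and 1 adjusted over the list alone; median 1.78; camera adjusted p = 1.07e-11, and adjusted p = 0.209 with an estimated correlation), with DDIT3 from 6.69 ± 6.32 to 113 ± 9.55 FPKM (log2 fold change 4.19, SE 0.41, adjusted p = 3.04e-05), ATF3 at 4.20, PPP1R15A at 3.42 and TRIB3 at 3.05. Without control replicate 1, where these genes were mostly higher than in the other controls, 20 and 1 rose and fell. Immediate early genes rose in 16 of 17 cases and none fell (16 and 0 adjusted over the list alone; camera adjusted p = 5.40e-12, and adjusted p = 0.179 with an estimated correlation), including JUN at 3.63 and KLF2 at 3.28. ER chaperone and unfolded protein response genes had 12 rises and 1 fall among 22 members (12 and 2 adjusted over the list alone; camera adjusted p = 2.39e-05, and adjusted p = 0.104 with an estimated correlation), with HSPA5 at 1.93 (adjusted p = 5.34e-06) and DNAJB9 at 2.31. NF-kB genes had 10 rises and 1 fall among 15 members (10 and 1 adjusted over the list alone; camera adjusted p = 0.000135, and adjusted p = 0.209 with an estimated correlation), with CXCL8 from 0.253 ± 0.0681 to 8.63 ± 0.418 FPKM and IL1A at 1.56. Cholesterol genes had 3 rises and 10 falls among 25 members (3 and 10 adjusted over the list alone; camera adjusted p = 0.0888). INSIG1 changed by -1.26 and HMGCS1 by -0.70. ANGPTL4 was up by 4.10, whereas SCD (-0.35 ± 0.16), CPT1A (0.29 ± 0.13), PDK4 (-0.34 ± 0.26), COL1A1 (0.078 ± 0.10), TGFB1 (0.15 ± 0.17) and ACTA2 (0.18 ± 0.12) did not pass the test. limma called 4307 genes, 2075 up and 2232 down (4538 with the trend removed; 4612 without both libraries that stand apart). Without control replicate 2 or 3 the number was 2474 or 2650, and with library totals set equal 1228 rose and 3274 fell. Of 13 named calls here, 12 held in all 12 fits that left out a library. In PA+OA against control, the call lost in some of these fits was HMGCS1 (highest limma adjusted p 0.0716), without control replicate 2, control replicate 3 and PA+OA replicate 1. CPT1A (0.39, adjusted p = 0.00897) passed the test without both libraries that stand apart, though not as deposited. Cholesterol genes had 0 to 1 rise without control replicates 2 or 3 or PA+OA replicates 1 or 2 and 6 falls without control replicate 2.

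With BMS-309403 and palmitate together, limma called 1306 genes against control, of which 565 rose and 741 fell (2279 with the trend removed; 2149 without both libraries that stand apart). The integrated stress response list had 17 rises and 1 fall among 25 members (19 and 1 adjusted over the list alone; camera adjusted p = 1.64e-11, and adjusted p = 0.111 with an estimated correlation), with ATF3 at 3.19, DDIT3 at 2.27 and TRIB3 at 1.54, and immediate early genes had 11 rises and 0 falls among 17 members (14 and 0 adjusted over the list alone; camera adjusted p = 1.64e-11, and adjusted p = 0.0843 with an estimated correlation). JUN changed by 2.89. With control replicate 1 left out, 18 and 1 integrated stress response genes rose and fell. ANGPTL4 was up from 7.33 ± 0.269 to 47.5 ± 9.64 FPKM (log2 fold change 2.52, SE 0.21, adjusted p = 4.59e-05), PDK4 by 1.02, CPT1A by 0.62 and CXCL8 by 1.62. The oxidation and PPAR list passed upward (5 of 21 rose and 0 fell; 5 and 0 adjusted over the list alone; camera adjusted p = 0.0301, and adjusted p = 0.111 with an estimated correlation), as did cholesterol genes (7 of 25 rose and 0 fell; 10 and 0 adjusted over the list alone; camera adjusted p = 4.50e-05, and adjusted p = 0.0545 with an estimated correlation). INSIG1 changed by 1.05. HMGCS1 (0.33 ± 0.19), HSPA5 (0.40 ± 0.15), SCD (0.38 ± 0.16), COL1A1 (-0.072 ± 0.10), TGFB1 (-0.15 ± 0.17) and ACTA2 (-0.087 ± 0.12) did not pass the test.

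Further lists fell in PA+BMS against control. Of 5 measured cholangiocyte and progenitor markers, 0 rose and 4 fell (0 and 5 adjusted over the list alone; camera adjusted p = 7.11e-05, and adjusted p = 0.0545 with an estimated correlation). KRT7 changed by -1.60. Heat shock genes had 0 rises and 6 falls among 15 members (0 and 6 adjusted over the list alone; camera adjusted p = 0.00101, and adjusted p = 0.269 with an estimated correlation). HSPA1A changed by -2.14 and BAG3 by -0.67. Interferon genes had 0 rises and 6 falls among 14 members (0 and 7 adjusted over the list alone; camera adjusted p = 0.00204, and adjusted p = 0.0545 with an estimated correlation). IFIT1 changed by -1.36 and ISG15 by -1.52. Matrix genes had 2 rises and 6 falls among 19 members (2 and 7 adjusted over the list alone; camera adjusted p = 0.0256, and adjusted p = 0.251 with an estimated correlation). FN1 changed by -0.96 and CYR61 by 1.42. Ribosomal protein and nuclear oxidative phosphorylation lists passed downward with no member past limma's gene-wise test, where RPL3 was at -0.28 ± 0.17 and SDHA at -0.34 ± 0.16 (camera adjusted p = 0.00446, and adjusted p = 0.543 with an estimated correlation for the first; camera adjusted p = 0.0416, and adjusted p = 0.543 with an estimated correlation for the second). Also passing, but upward, were p53 and apoptosis genes (6 of 17 rose and 1 fell; 7 and 1 adjusted over the list alone; camera adjusted p = 0.00408, and adjusted p = 0.0545 with an estimated correlation) with GADD45A at 2.30, and NRF2 targets (5 of 19 rose and 1 fell; 5 and 1 adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.210 with an estimated correlation) with SLC7A11 at 1.15. The count of called genes was 766, 721 and 648 without control replicates 1, 2 and 3, 761 and 729 without PA+BMS replicates 1 and 2, and 2323 without PA+OA replicate 1. Of 18 named calls here, 14 held in all 12 fits that left out a library. In PA+BMS against control, calls lost in some of these fits were BAG3, CPT1A, PDK4 and SLC7A11 (highest limma adjusted p 0.0508 to 0.128), without control replicate 2 (3), control replicate 3 (3), PA+BMS replicate 3 (2), control replicate 1 (1), PA+BMS replicate 1 (1) and PA+BMS replicate 2 (1). With the trend removed, BAG3 was no longer called (adjusted p 0.125). Without both libraries that stand apart, BAG3 was not called (adjusted p 0.0557). HSPA5 (0.36, adjusted p = 0.0324) passed the test with the trend removed, though not as deposited. HSPA5 (0.40, adjusted p = 0.0269) passed the test without both libraries that stand apart, though not as deposited. List members that rose and fell numbered 12 and 0 for cholesterol genes and 8 and 1 for NRF2 targets with the trend removed. They numbered 11 and 0 for cholesterol genes without the libraries that stand apart. Omitting a library moved by over 1.5 times the number of oxidation and PPAR targets that rose (1 to 3 without control replicates 1, 2 or 3 or PA+BMS replicates 2 or 3) and cholesterol genes that rose (4 without control replicate 3, and 11 without PA+OA replicate 1). It also moved heat shock genes that fell (2 to 3 without control replicates 2 or 3 or PA+BMS replicates 1, 2 or 3) and interferon genes that fell (3 without control replicate 2 or PA+BMS replicate 1). Moved alike were p53 genes that rose (3 without control replicates 2 or 3 or PA+BMS replicates 1 or 2) and NRF2 targets that rose (1 to 3 without control replicates 1, 2 or 3 or PA+BMS replicates 1, 2 or 3).

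The direct comparison of PA+BMS with PA+OA tested how the additions differed. The heat shock genes HSPA6 (from 24.6 ± 3.70 in PA+OA to 0.206 ± 0.0709 FPKM in PA+BMS), HSPA1A and HSPA1B led the falls, at -4.40, -4.01 and -3.48 on the log2 scale. INSIG1 (log2 fold change 2.31, SE 0.11, adjusted p = 2.85e-07) and MT-ND6 at 1.93 were among the leading rises. Cholesterol genes were higher in PA+BMS (14 of 25 rose and 0 fell; 14 and 2 adjusted over the list alone; camera adjusted p = 0.000321, and adjusted p = 0.139 with an estimated correlation). HMGCS1 changed by 1.03 and SCD, of the desaturation list, by 0.73. ER chaperone genes were lower (2 of 22 rose and 11 fell; 2 and 11 adjusted over the list alone; camera adjusted p = 0.000551, and adjusted p = 0.139 with an estimated correlation). HERPUD1 changed by -2.51 and HSPA5 by -1.52. Lower too were integrated stress response genes (2 of 25 rose and 14 fell; 2 and 14 adjusted over the list alone; camera adjusted p = 0.00125, and adjusted p = 0.562 with an estimated correlation), immediate early genes (1 of 17 rose and 11 fell; 1 and 11 adjusted over the list alone; camera adjusted p = 0.00125, and adjusted p = 0.562 with an estimated correlation) and NF-kB genes (1 of 15 rose and 10 fell; 1 and 10 adjusted over the list alone; camera adjusted p = 0.00135, and adjusted p = 0.476 with an estimated correlation). DDIT3 at -1.92, TRIB3 at -1.50, KLF2 at -1.66, CXCL8 at -1.32 and ANGPTL4 at -1.57 fell, and PDK4 at 1.35 and CPT1A at 0.34 rose.

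Heat shock genes as a list were lower in PA+BMS than in PA+OA (1 of 15 rose and 9 fell; 1 and 9 adjusted over the list alone; camera adjusted p = 0.00847, and adjusted p = 0.562 with an estimated correlation), as were ribosomal protein genes (0 of 27 rose and 19 fell; 0 and 19 adjusted over the list alone; camera adjusted p = 0.000321, and adjusted p = 0.635 with an estimated correlation; 0 and 2 without the libraries that stand apart; RPS16 at -0.94) and nuclear oxidative phosphorylation genes (2 of 25 rose and 12 fell; 2 and 12 adjusted over the list alone; camera adjusted p = 0.0323, and adjusted p = 0.635 with an estimated correlation; 0 and 2 without those libraries). COL1A1 (-0.15 ± 0.10), TGFB1 (-0.31 ± 0.17) and ACTA2 (-0.27 ± 0.12) did not pass the test. In all 5878 genes were called, 2744 up and 3134 down, against 4020 with the trend removed and 2523 without both libraries that stand apart. PA+OA replicate 1 and PA+BMS replicate 3 each moved the number, to 3586 and 3041 when left out, and with library totals set equal 4577 rose and 1488 fell. Of 17 named calls here, 16 held in all 12 fits that left out a library. Between PA+BMS and PA+OA, the call lost in some of these fits was CPT1A (highest limma adjusted p 0.176), without 11 of the 12 libraries in turn, all but PA+OA replicate 3. Without both libraries that stand apart, CPT1A was not called (adjusted p 0.358). TGFB1 (0.26, adjusted p = 0.0397, in the opposite direction) passed the test with the trend removed, though not as deposited. List members that rose and fell numbered 1 and 6 for immediate early genes and 0 and 11 for ribosomal protein genes with the trend removed. They numbered 0 and 6 for immediate early genes without the libraries that stand apart. Leaving out one library moved by over 1.5 times the number of immediate early genes that fell (7 without PA+BMS replicate 3) and ribosomal protein genes that fell (2 to 5 without PA+OA replicate 1 or PA+BMS replicate 3). It also moved nuclear oxidative phosphorylation genes that fell (2 to 3 without PA+OA replicate 1 or PA+BMS replicate 3). Cholesterol genes had 3 falls without PA+OA replicate 3.

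**Figure D4:**
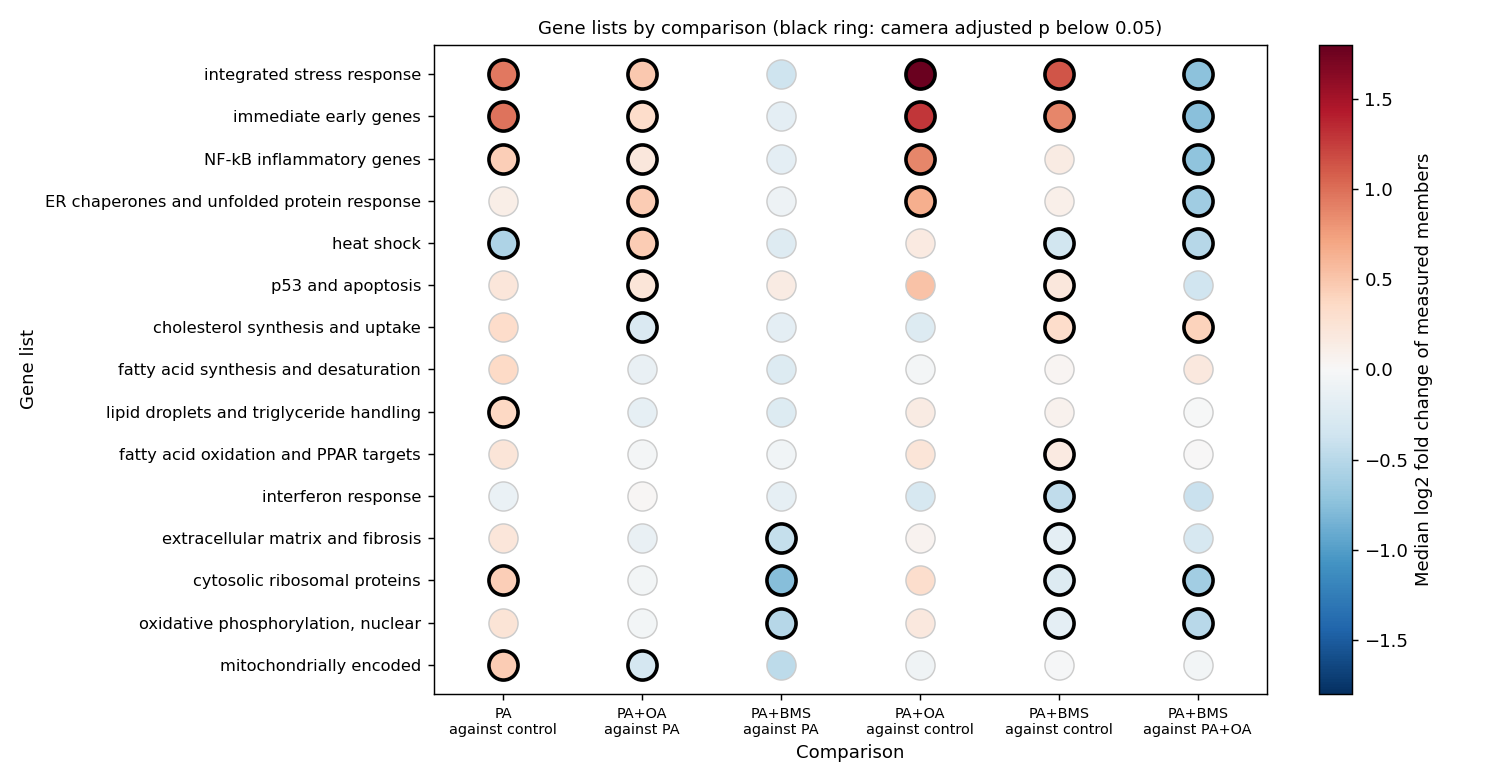
Median log2 fold change of the measured members of 15 gene lists in each of the 6 comparisons, as colour, with a black ring where camera's adjusted p with its preset correlation is below 0.05. The integrated stress response has a median of 1.78 in PA+OA against control, and cytosolic ribosomal proteins one of -0.76 in PA+BMS against PA.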

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

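The 3 tests of why hepatocyte genes were low were chosen after the result was seen, as were the settings that remove the GC trend or leave out both libraries that stand apart and the allowance for the SE in the test of poly(A) selection. The other bounds were set before their results were seen. Genes that oleate and BMS-309403 moved in opposite directions under palmitate, each past its own limma test and the direct test, numbered 73. Of these, 56 rose with oleate and fell with BMS-309403, and 17 did the reverse. Of 484 genes called in both comparisons, 411 moved in the same direction. In 100 simulations with no effect of either addition, at most 0 genes moved in opposite directions and 1 in the same. Near 0 by design, this cannot judge 73. Independent lists would share 256 and 255, so 73 lies below and 411 above. The PA libraries are too few to split, so part of any excess can come from sharing them, and none is read as a shared effect. In the direct comparison of the additions, the cholesterol synthesis and uptake list differed (camera adjusted p = 0.000321; 14 of 25 members higher in PA+BMS), as did the ER chaperone and unfolded protein response list (camera adjusted p = 0.000551; 11 of 22 lower), although with an estimated correlation the adjusted p was 0.139 for each.

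Between PA+BMS and PA, 6463 genes were called. With each library's trend in GC content and length removed 2750 were called, of which 1930 were among the first, under the bound of 50% set for that trend as a main contributor. The trend may account for part of the change but not the whole, and since GC content moves with the groups, a biological shift along GC and a library effect cannot be told apart. Without PA+BMS replicate 3 there were 3703, between the bounds of 50% and 67%, and without it and PA+OA replicate 1 there were 6508, which leaves that library open as a part of the cause. An effect of 24 h with the inhibitor or with its solvent by itself was not tested.

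Of 28 hepatocyte genes, 2 reached 1 FPKM in every library. The tables argue against too little depth, because 3 reads of any listed gene were worth at most 0.229 FPKM. Of 16 cholangiocyte and progenitor markers 5 reached 1 FPKM in every library and 11 stayed under it in every library. Whether an undifferentiated or bile duct-like culture is the reason is therefore not decided. Cells other than the labelled line stay open too, since no reference profile of the line was used here.

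Histone genes rose in 19 of 30 cases in PA+OA against PA, with a median log2 change of 1.15. Without PA+OA replicate 1 the median was 1.17 over 22 measured genes, of which 13 rose. This argues against that library alone, although the filter can favour genes high in PA+OA. Less complete poly(A) selection is open. Other non-polyadenylated RNA had 1.095 times its share in PA (SE 0.151), under the bound of 1.1 by less than its SE. Mitochondrial ribosomal RNA was 2.20 times that in PA, but PA+BMS replicate 3, at 1.51%, had no histone rise. More cells in S phase is open (median log2 change 0.0331 over 12 S-phase genes, SE 0.0863).

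For each comparison, all 10 splits of its 6 libraries into 3 and 3 were fitted, and 1 of 10, the real one, gave as many called genes. In PA against control the real value was 3272 genes and the highest other split gave 1. In PA+OA against PA the real value was 938 genes and the highest other split gave 1. In PA+BMS against PA the real value was 6463 genes and the highest other split gave 1. In PA+OA against control the real value was 4307 genes and the highest other split gave 1. In PA+BMS against control the real value was 1306 genes and the highest other split gave 0. In PA+BMS against PA+OA the real value was 5878 genes and the highest other split gave 0. With 10 splits a share under 0.05 cannot be reached.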

How the results depend on the processing

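Settings that remove the GC trend, leave out both libraries that stand apart or use voom were chosen after seeing the data, and the others were planned. The number of called genes stayed within 1.5 times its reported value in PA+OA against control under all settings other than leaving out a library, and elsewhere moved as follows; the cause was not tested. Palmitate-changed genes that an addition moved toward control are given as moved back. With no filter, PA against control gave 1599, moved back with PA+OA gave 65, moved back with PA+BMS gave 816. With only the 2 groups compared in the fit, PA against control gave 5906, PA+OA against PA gave 464, PA+BMS against PA+OA gave 2066, moved back with PA+OA gave 81, moved back with PA+BMS gave 4234. With the GC and length trend removed, PA against control gave 1948, PA+OA against PA gave 1583, PA+BMS against PA gave 2750, PA+BMS against control gave 2279, moved back with PA+BMS gave 581. Without both libraries that stand apart, PA against control gave 6687, PA+OA against PA gave 2977, PA+BMS against control gave 2149, PA+BMS against PA+OA gave 2523, moved back with PA+OA gave 1474, moved back with PA+BMS gave 4619. With a filter at 5 FPKM, PA+BMS against control gave 853. With library totals set equal, moved back with PA+OA gave 62. Leaving out each library in turn gave these ranges: PA against control 798 to 5348, PA+OA against PA 465 to 1900, PA+BMS against PA 3698 to 7402, PA+OA against control 2474 to 5008, PA+BMS against control 648 to 2323, PA+BMS against PA+OA 3041 to 6240, moved back with PA+OA 28 to 783, moved back with PA+BMS 412 to 4158. When that leaves a group with 2 libraries, the spread is still pooled over all groups. With voom on recovered reads, where 100% of values came out whole, the counts were PA against control 3516, PA+OA against PA 966, PA+BMS against PA 6620, PA+OA against control 4417, PA+BMS against control 1435, PA+BMS against PA+OA 5959. A count model had been planned only for a file of counts and was not run, so the recovered reads were tested with voom alone. Genes a setting filters out have no value there. Depth limits low genes, but FABP4 was at most 0.0864 FPKM.

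Replicate numbers were shared by the groups, but same-numbered libraries did not deviate together in all cases: 9 of 18 pairs had a residual correlation over 0.1 (range -0.28 to 0.56), and 9 of 12 libraries correlated best with their own number, a hint from the data and not the design. With the number as a replicate block, the values were PA against control 4652, PA+OA against PA 1139, PA+BMS against PA 7083, PA+OA against control 5242, PA+BMS against control 1704, PA+BMS against PA+OA 6557, moved back with PA+OA 208, moved back with PA+BMS 3560.

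Among single genes and lists, 5757 values of named genes and 1374 of lists kept their direction and side of the threshold, 253 and 88 lost their call and 46 and 32 gained one. Signs differed in the following cases, in log2 change for genes; the cause was not tested. With library totals set equal this was so in PA against control for ACTA2 (-0.058), COL1A1 (-0.045) and HSPA5 (-0.046), in PA+BMS against PA for ACTA2 (0.014), COL1A1 (0.066), CXCL8 (0.071) and SCD (0.36), in PA+BMS against PA+OA for COL1A1 (0.16) and TGFB1 (0.024), in PA+BMS against control for COL1A1 (0.021), in PA+OA against control for COL1A1 (-0.14) and TGFB1 (-0.081). With the GC and length trend removed this was so in PA against control for ACTA2 (-0.13), COL1A1 (-0.059), TGFB1 (-0.073) and the list of phospholipid and sphingolipid synthesis (adjusted p = 0.202), in PA+BMS against PA for ACTA2 (0.12), COL1A1 (0.093), PDK4 (-0.039), TGFB1 (0.12), TRIB3 (0.061), the list of integrated stress response (adjusted p = 0.942) and the list of phospholipid and sphingolipid synthesis (adjusted p = 0.612), in PA+BMS against PA+OA for ACTA2 (0.044), COL1A1 (0.048) and TGFB1 (0.26, called at adjusted p = 0.0397), in PA+OA against control for ACTA2 (-0.054), COL1A1 (-0.014) and TGFB1 (-0.21), in PA+BMS against control for COL1A1 (0.033) and TGFB1 (0.050), in PA+OA against PA for COL1A1 (0.045) and the list of fatty acid oxidation and PPAR targets (adjusted p = 0.815). Without both libraries that stand apart this was so in PA+OA against PA for HMGCS1 (0.12), in PA+OA against control for TGFB1 (-0.070). Under quantile normalization this was so in PA against control for HSPA5 (-0.086), in PA+BMS against PA for SCD (0.61) and TRIB3 (0.074). Under median-of-ratios scaling this was so in PA+BMS against PA for SCD (0.038). For ACTA2, PA+BMS against control, the fits without a library ran from -0.17 to 0.021. For HMGCS1, PA+OA against PA, the fits without a library ran from -0.16 to 0.12. For SCD, PA+BMS against PA, the fits without a library ran from -0.13 to 0.092. For TGFB1, PA+OA against control, the fits without a library ran from -0.070 to 0.29. For the list of fatty acid oxidation and PPAR targets, PA+OA against PA, the fits without a library ran from 0.700 to 0.961 in adjusted p.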

Other observations

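All tests here use lists that were planned; which lists and genes are given, PDGFRB, CSF1R and CDH5 among them, was chosen only after the results were seen. Cell cycle genes with palmitate had 2 rises and 8 falls among 24 measured members (4 and 9 adjusted over the list alone, camera adjusted p = 0.0995; 1 and 6 with the GC and length trend removed, 7 and 13 without both libraries that stand apart). The log2 changes of TOP2A (-1.21), a DNA topoisomerase, CCNA2 (-0.73), cyclin A2, and CCND1 (-1.07), cyclin D1, had the smallest p. In PA+BMS against PA the list had 5 and 7 (5 and 6 adjusted over the list alone, camera adjusted p = 0.665; 5 and 1 with the trend removed, 6 and 7 without both). Phospholipid and sphingolipid genes had 10 rises and 5 falls among 23 in PA+BMS against PA (10 and 5 adjusted over the list alone, camera adjusted p = 0.665), but 1 and 3 with the trend removed, 7 and 8 without both. The sphingosine kinases SPHK1 (-1.30) and SPHK2 (-0.66) fell, and UGCG (0.81), which makes glucosylceramide, and SGMS1 (0.66), a sphingomyelin synthase, rose. With palmitate the list had 3 and 4 (3 and 4 adjusted over the list alone, camera adjusted p = 0.832; 3 and 1 with the trend removed, 7 and 8 without both). Autophagy and lysosome genes had 6 rises and 2 falls among 20 with palmitate (7 and 2 adjusted over the list alone, camera adjusted p = 0.235; 2 and 1 with the trend removed, 11 and 2 without both). Here the autophagy receptor SQSTM1 (0.88) rose and LAMP2 (-0.63), a lysosomal membrane protein, fell. LXR targets had 4 rises and 1 fall among 6 with palmitate (4 and 1 adjusted over the list alone, camera adjusted p = 0.245; 1 and 1 with the trend removed, 4 and 1 without both), where LPCAT3 (0.61) and SREBF1 (0.56) rose and MYLIP (-0.58) fell. With single libraries left out, list counts moved by over 1.5 times with palmitate for cell cycle genes (4 rises without PA+OA replicate 1, 3 to 5 falls without control replicates 2 or 3 or PA replicates 1, 2 or 3), autophagy genes (1 to 3 rises without control replicates 2 or 3 or PA replicates 1, 2 or 3) and LXR targets (1 to 2 rises without control replicates 2 or 3 or PA replicates 1, 2 or 3). This held for phospholipid and sphingolipid genes too (1 rise and 0 to 2 falls without control replicates 2 or 3 or PA replicates 1, 2 or 3 or PA+BMS replicate 2, 7 rises without PA+OA replicate 1). It held in PA+BMS against PA for that list (4 rises without PA replicate 2 or PA+BMS replicate 3, 3 falls without PA+BMS replicate 3, 9 falls without PA+OA replicate 1) and for the cell cycle (3 to 4 falls without PA replicate 2 or PA+BMS replicate 3). Leaving out a library ended the limma calls of LAMP2, MYLIP and SREBF1 (highest adjusted p 0.0932, 0.0673 and 0.135 in this order), in at least 1 case each without PA replicate 1, control replicate 2, PA replicate 2 and control replicate 3. Removing the GC and length trend ended the calls of LAMP2 (adjusted p = 0.155), SREBF1 (adjusted p = 0.0803), UGCG (adjusted p = 0.0602), SPHK2 (adjusted p = 0.0943) and SGMS1 (adjusted p = 0.145).

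Hypoxia and glycolysis genes had 4 rises and 0 falls among 20 in PA+OA against PA (4 and 0 adjusted over the list alone, camera adjusted p = 0.118). These were the glucose transporters SLC2A3 (0.76) and SLC2A1 (0.62), ADM (0.80), adrenomedullin, and ANKRD37 (0.80). Metallothioneins had 2 rises and 0 falls among 4 (2 and 0 adjusted over the list alone, camera adjusted p = 0.0603), MT1X (0.82) and MT1E (0.81), which have near-identical copies, so their reads are uncertain. Xenobiotic metabolism genes had 2 and 0 among 6 (2 and 0 adjusted over the list alone, camera adjusted p = 0.599), ALAS1 (0.53) and TIPARP (0.74). Markers of other liver cell types were mostly under the tested level, with 2 of 12 stellate cell and fibroblast, 1 of 12 macrophage and leukocyte and 1 of 12 endothelial markers measured. In PA+BMS against control PDGFRB (-0.78), CSF1R (-0.83) and CDH5 (-0.82) fell, 1 from each list, and none rose. All 3 fell in PA+BMS against PA as well (-0.78, -0.87 and -0.66). PDGFRB (-0.65) and CSF1R (-0.86) were lower in PA+BMS than in PA+OA, whereas CDH5 fell with oleate too, by 0.71 against PA (camera adjusted p = 0.0279, and adjusted p = 0.207 with an estimated correlation) and 0.86 against control. Against control, the camera adjusted p of these lists with BMS-309403 was 0.0228, 0.0294 and 0.0290, and adjusted p = 0.111 for each with an estimated correlation. Lists of 1 or 2 measured genes say little about a cell type. The hypoxia list had 2 rises without PA replicate 3. Leaving out a library ended the limma calls of SLC2A1, ANKRD37, MT1X, MT1E, ALAS1 and TIPARP (highest adjusted p 0.0626, 0.0837, 0.140, 0.186, 0.0564 and 0.156 in this order), in at least 1 case each without PA replicate 3, PA replicate 2, PA replicate 1, PA+BMS replicate 2, PA+OA replicate 2, PA+OA replicate 3, control replicate 2, control replicate 3, PA+BMS replicate 1, control replicate 1 and PA+OA replicate 1.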
